A study of Homo sapiens with 6 samples.

How the data were processed

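RNA sequencing was done on OCI-AML2, an established human acute myeloid leukemia cell line, carrying either a control shRNA (shCtrl, 3 libraries) or an shRNA against ADGRE2 (shADGRE2, 3 libraries). A short hairpin RNA is processed in the cell into a small interfering RNA that lowers the level of its target mRNA. Per the labels' protocols, total RNA was extracted with RNAiso Plus and libraries were made with the NEBNext Ultra II RNA kit; the labels do not say whether poly(A) selection or rRNA depletion was used.

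The deposited values are raw counts of read pairs per gene, one library per file. Per the file headers, counting was done with featureCounts 2.0.1 over exons of the GENCODE 35 annotation, with pairs counted as fragments and without the strand option. Per the file headers, the options that count pairs mapping to several places or overlapping several genes were not set, and the name of the aligned file says that it held unique pairs. Genes with a near-identical copy therefore lose counts. Pairs that overlap both a gene and an antisense partner are lost too, and the other pairs are assigned by position without regard to strand. Per the submitters' processing notes, FastQC 0.11.5, Trim Galore 0.6.5 and HISAT2 2.2.1 were used, and the builds hg38 and mm10 were named; the role of the mouse build is not given in the sources used here. Gene coordinates are those of the file headers' annotation on hg38. The files hold 60656 gene identifiers; 42020 of them (69.3%) matched a symbol in a table of gene names, and 96.3% were in GENCODE release 29, from which gene types and GC content were taken.

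Library totals were 14906481 to 16590912 counts. Replicates were compared first: between libraries of one group other than shADGRE2 replicate 2, the chi-square per gene was 2.41 to 3.01, where sampling noise alone gives about 1, so no library was counted as a copy of another. The replicate numbers were checked for pairing by correlating same-numbered deviations from the group means, which are given with the alternatives in the closing section.

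Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test on the deposited counts, with TMM normalization, the edgeR expression filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05 over all genes tested. The design, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The primary comparison used all 6 libraries with the group as the only term. Because shADGRE2 replicate 2 stood apart in composition, the planned leave-one-out fit without it, over 5 libraries, was used for naming and describing genes; this choice was made after the values were seen. Alternatives were DESeq2 1.42.0, limma 3.58.1 voom, other normalizations and filters, a fold threshold, a replicate block, each library left out, and 2 added after the data were seen: voom with library quality weights, and offsets for exon length and GC content. Fold changes are shADGRE2 over shCtrl on the log2 scale with their standard errors; levels are counts scaled by the TMM-adjusted library size (CPM). A log2 ratio of a single library to the control mean was computed after adding 0.5 CPM, and for shADGRE2 replicate 2 again with library totals in place of TMM, which was added after the data were seen.

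A total of 38 gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, wherever at least 5 members were tested, with adjustment over the lists. Camera with an estimated correlation and with ranks, and fry, were run beside it. For each list, members that passed edgeR's test were counted over all genes tested and again adjusted over the list alone. Named genes are the ADGRE family, the 10 genes that rose and the 10 that fell most among protein-coding genes with adjusted p under 0.05, a group mean of at least 10 CPM and no overlap between the 3 values of each group, up to 4 members per list by smallest adjusted p, and 13 names fixed in advance (DUSP1, DNAJB1, HSPA1A, HSPA1B, HSPA8, FOS, JUN, JUNB, FOSL1, MYC, HSPA5, DDIT3 and ATF4). The overlap condition was kept over all 6 libraries.

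The tests were checked on simulated counts in which 50 genes at each of 4 fold sizes were changed. With 6 well-behaved libraries, 62.0%, 64.0%, 88.0% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered. With 1 library deviating as shADGRE2 replicate 2 does, the recovery was 0%, 0%, 12.0% and 52.0%. With the 5 libraries it was 46.0%, 66.0%, 86.0% and 98.0%, with 4 false calls among 14987 genes. In a separate simulation of 5 libraries, camera gave an adjusted p of 5.53e-28 for a list of 30 genes raised 1.3-fold and called 0 of 30 random lists. Genes were drawn independently there, so this check says nothing about false calls on lists whose genes move together. Results for some genes are not reported here.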

Results

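Gene expression was measured in OCI-AML2 cells with a control shRNA or an shRNA against ADGRE2, a receptor of the adhesion G-protein-coupled receptor family that is found on myeloid cells. The comparison addresses what this receptor does for acute myeloid leukemia cells, and the title of the series names proteostasis, the upkeep of cellular proteins, as its subject. Each group had 3 libraries, with totals of 15721478 to 16590912 counts for shCtrl and 14906481 to 15879360 counts for shADGRE2. The labels do not say whether 1 or more hairpins were used against ADGRE2, nor that the libraries came from separate cultures, so p-values measure only the spread between these samples.

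The target was lower in every knockdown library. ADGRE2 (ENSG00000127507.18; hg38 chromosome 19, 14732392 to 14778560, minus strand, protein-coding) stood at 24.6, 27.4 and 24.1 CPM in shCtrl replicates 1, 2 and 3 and at 13.7, 8.85 and 13.5 CPM in shADGRE2 replicates 1, 2 and 3, from 109 to 466 counts per library. The knockdown mean of 11.99 ± 2.72 CPM (SD, n = 3) was 47.3% of the control mean of 25.4 ± 1.81 CPM (SD, n = 3). An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest that this design allows. Over all 6 libraries edgeR gave a log2 fold change of -1.08 ± 0.20 (SE) with an adjusted p of 0.194, and without shADGRE2 replicate 2 it gave -0.90 ± 0.10 (SE) with an adjusted p of 2.99e-07. Of its relatives in that 5-library edgeR fit, ADGRE4P, a pseudogene, rose by a log2 value of 0.25 (adjusted p = 0.0103) and ADGRE3 rose from 0.434 ± 0.0849 CPM (SD, n = 3) to 1.48 and 1.60 CPM (adjusted p = 0.00259), but both were below the control mean in replicate 2, at 13.8 CPM for ADGRE4P and 0 counts for ADGRE3. ADGRE5, which encodes CD97, had a log2 fold change of 0.10 (adjusted p = 0.193), and ADGRE1 had too few counts to be tested. These genes are related in sequence, so pairs shared between copies were not counted.

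Beside the controls, shADGRE2 replicates 1 and 3 had lower levels of the AP-1 genes JUN and FOS, the co-chaperone DNAJB1 and the constitutive chaperone HSPA8. The creatine transporter gene SLC6A8 and the glycolysis and hypoxia genes ALDOC and BNIP3 were lower there too. Higher levels were seen in the same libraries for the monocyte and macrophage genes CD14, MERTK and LYZ, the chemokine CCL2 and the ATF4 targets STC2 and SLC7A11. Over all 6 libraries edgeR called 0 genes. The remaining knockdown library, shADGRE2 replicate 2, had the lowest ADGRE2 level, 34.9% of the control mean. With TMM it shared the direction of JUN, FOS, DNAJB1, SLC6A8, ALDOC, CD14, MERTK, CCL2 and STC2. All of these but FOS and STC2 are among the genes listed below under no overlap over all 6 libraries, a condition that fixes this direction. JUN, FOS and DNAJB1 were also names fixed in advance. With library totals in place of TMM, STC2 stood at 0.964-fold of the control mean. Replicate 2 did not share the direction of HSPA8 and BNIP3, at 1.36- and 1.38-fold of the control mean with TMM, or of LYZ and SLC7A11, at 0.480- and 0.967-fold. It differed from all other libraries in composition: 20.4% of its counts fell on ribosomal protein genes against 11.05% to 12.3% elsewhere, 20086 genes had a count against 22815 to 23221, and its TMM factor was 0.779 against 1.04 to 1.06. The count-weighted median exon length was 4315 bases in this library and 5030 to 5093 in the others. Values of this library depend on that factor: with library totals as the only scaling, a comparison added after the data were seen, its log2 ratios to the control mean were lower by a median of 0.41. The medians of 12 of 32 lists then changed from above 0 to below it in replicate 2: DNAJ co-chaperones, dual-specificity phosphatases, ER unfolded protein response, ATF4 targets, autophagy and lysosome, DNA replication, mitosis, cholesterol synthesis, interferon-stimulated, NF-kB, monocyte and mitochondrially encoded genes. Replicate 2 values below are scaled by TMM unless stated, and small ones do not settle a direction.

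In the comparison of all 6 libraries, edgeR called 0 of 14815 genes at an adjusted p under 0.05, with 1482 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0716. DESeq2 called 343 genes, 172 higher and 171 lower, and limma voom called 0, with the same libraries. Leaving out shADGRE2 replicate 2, edgeR called 3873 of 15267 genes, of which 2012 rose and 1861 fell, and 406 were at least 2-fold changed (215 up and 191 down). The biological coefficient of variation was 26.2% with that library and 4.29% without it. Leaving out any other single library left the count at 0. Of the 3873 genes, 2412 (62.3%) had the same direction in the omitted library, where simulated libraries with no knockdown effect gave 54.0% on average and 55.9% at most. For the 406 genes the share was 69.5%, against 56.4% on average and 60.6% at most. It was 62.3% (134 of 215) for those that rose and 77.5% (148 of 191) for those that fell, and the simulated values were not split by direction. With library totals for replicate 2 the shares were 59.8% of the 3873 and 65.8% of the 406 genes. By that scaling 42.1% of the 2012 genes that rose and 79.0% of the 1861 that fell had the same direction, beside 60.1% and 64.6% with TMM. Among the 2-fold genes the shares were 50.7% for those that rose and 82.7% for those that fell. The median log2 ratio of all tested genes in replicate 2 was then -0.42, so a downward shift enters these shares. The simulation was not repeated for library totals. The simulated values already include the effect of shared controls. However, the simulated genes were those with the smallest p, taken in equal number and without a condition on fold. The 56.4% and 60.6% are therefore not for genes chosen as the 406 were. Each gene was also drawn independently, and the deviations of replicate 2 were shuffled over genes. Real genes move in groups, such as the ribosomal protein genes, so the simulated range may be too narrow. Whether 62.3% or 69.5% exceeds chance cannot be told from it. From here on, "rose" and "fell" refer to edgeR's test over the 5 libraries, a choice made after the values were seen, and values of the omitted library are given beside the gene groups.

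**Figure D1:**
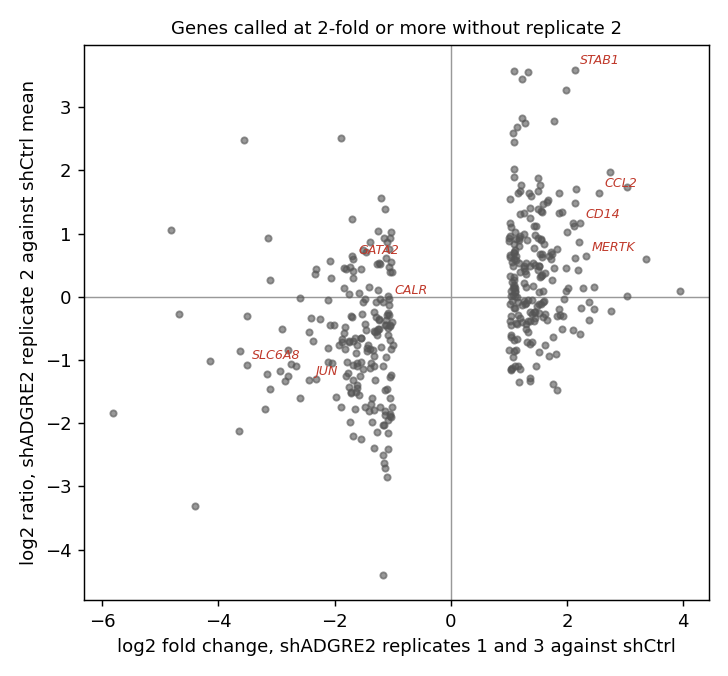
Each point is one of the 406 genes called at 2-fold or more without shADGRE2 replicate 2, with the log2 fold change of the 5-library fit on the horizontal axis and the log2 ratio of shADGRE2 replicate 2 to the control mean on the vertical axis. The same sign is seen for 282 of them (69.5%).

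Among protein-coding genes with a group mean of at least 10 CPM and no overlap between the groups, the 10 that rose most included several genes of monocytes and macrophages. CCL2, a chemokine that draws monocytes, rose 5.85-fold, from 4.81 ± 0.162 CPM (SD, n = 3) to a mean of 28.2 CPM in replicates 1 and 3, with 16.2 CPM in replicate 2. MERTK, a receptor for the uptake of dead cells, rose 5.04-fold, and CD14, the co-receptor for lipopolysaccharide, rose 4.67-fold, from 7.03 ± 0.208 CPM (SD, n = 3) to 32.8 CPM, with 16.4 CPM in replicate 2. C5AR1, the receptor for complement C5a, rose 4.47-fold, the scavenger receptor gene STAB1 4.37-fold, and the gelatinase gene MMP9 3.94-fold. IL1B rose 3.77-fold, PADI4, which encodes an enzyme that citrullinates histones, 3.64-fold, GAS7 3.36-fold and MCEMP1 2.90-fold. In these 10 genes replicate 2 lay at 1.62-fold (MERTK and GAS7) to 14.1-fold (STAB1) of the control mean, a direction that the condition of no overlap fixes. MMP9 reached the minimum level only through replicate 2 (7.24, 23.5 and 8.49 CPM). The edgeR adjusted p of these genes ran from 3.14e-07 for MMP9 down to 3.73e-15 for MCEMP1.

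Among the 10 that fell most under the same conditions, SLC6A8, the creatine transporter, fell 11.4-fold, from 49.7 ± 3.11 CPM (SD, n = 3) to 4.34 CPM in replicates 1 and 3, with 23.3 CPM in replicate 2. ALDOC, a glycolytic aldolase, fell 6.71-fold, JUN 5.41-fold, the small GTPase gene RHOB 4.25-fold and HSPA6, a heat-inducible HSP70, 4.03-fold. ARRDC3 was 3.79-fold lower, PFKFB4, a regulator of glycolysis, 3.11-fold, and NMUR1, the neuromedin U receptor, 3.07-fold. PUF60, a splicing factor, was also 3.07-fold lower, but its control values spread over 50.4 ± 29.1 CPM (SD, n = 3). DNAJB1 fell 2.91-fold. Replicate 2 lay between 0.363-fold (NMUR1) and 0.730-fold (RHOB) of the control mean for these 10 genes, which the same condition places below the controls. It left out genes such as BNIP3 and GATA2 that fell more than DNAJB1 but were above the controls in replicate 2. HSPA6 has a near-identical copy, HSPA7, and its value is uncertain for that reason. The edgeR adjusted p ran from 0.00014 for PUF60 to 5.79e-17 for JUN.

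**Figure D2:**
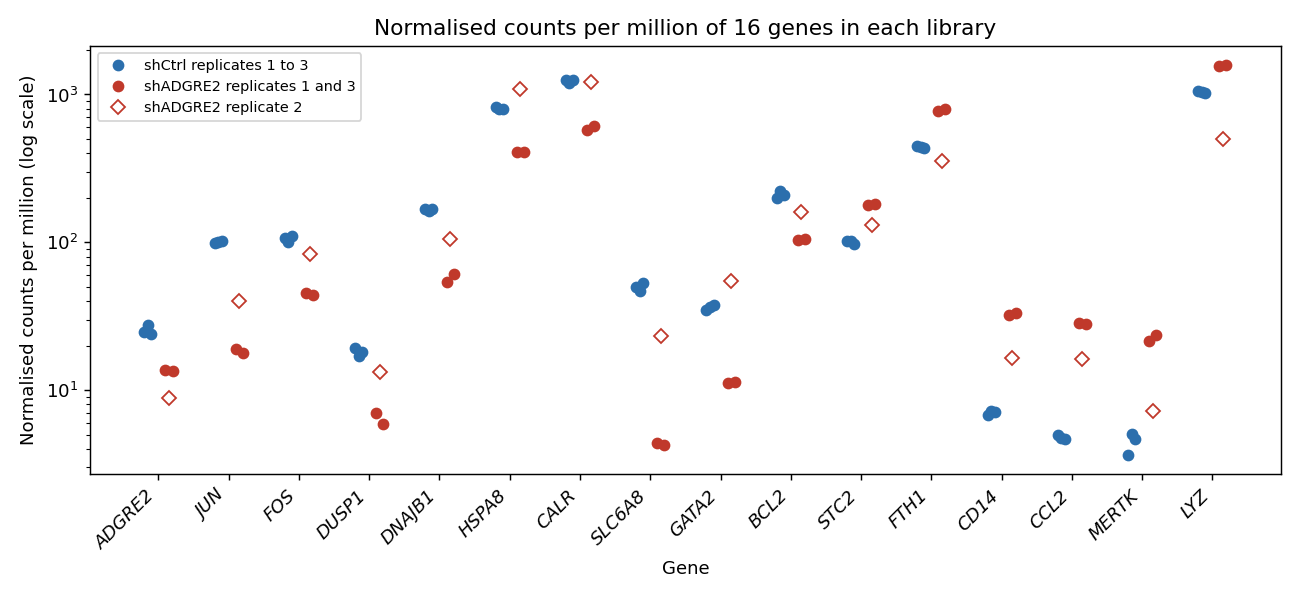
Normalised counts (CPM, log scale) of 16 genes in each of the 6 libraries; filled blue circles are the 3 control libraries, filled red circles are shADGRE2 replicates 1 and 3, and the open diamond is shADGRE2 replicate 2. JUN lies near 100 CPM in the controls, at 19.1 and 17.9 CPM in replicates 1 and 3 and at 39.8 CPM in replicate 2, whereas HSPA8 is at 1097 CPM in replicate 2, above the control mean of 808 CPM by this scaling.

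Genes of protein folding and turnover did not move as a block. Of 28 heat shock chaperones tested, 13 fell and 3 rose (15 and 5 adjusted over the list alone). HSPA8, which folds newly made proteins, fell 1.97-fold from 808 ± 15.4 CPM (SD, n = 3) to 409 CPM in replicates 1 and 3 (log2 -0.98 ± 0.04 SE; edgeR adjusted p = 1.68e-14). HSPH1 fell 1.88-fold, HSPB1, which encodes the small chaperone HSP27, 1.87-fold and HSPA6 4.03-fold. The camera test placed the list lower than other genes (adjusted p = 0.000639 and adjusted p = 0.126 with an estimated correlation). In replicate 2 the median of the list lay a log2 value of 0.73 above the control mean, with HSPA8 at 1.36-fold, HSPH1 at 1.38-fold and HSPB1 at 2.47-fold of it. With library totals the median was 0.31 and the genes stood at 1.01-, 1.03- and 1.84-fold, so a rise of HSPA8 and HSPH1 in replicate 2 rests on its TMM factor. With that library included the list was not called (adjusted p = 0.589). HSPA1A and HSPA1B, the main inducible HSP70 genes, had 0 and 1 counts over all 6 libraries. They lie in the major histocompatibility complex on chromosome 6, where 30 of 181 protein-coding genes reached 10 counts in any library, against 62.3% of protein-coding genes elsewhere, so no statement on their expression can be drawn from these counts.

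Of 34 DNAJ co-chaperones, which guide substrates to HSP70, 5 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.597), and the list's median (0.09) and mean (-0.002) had opposite signs. The median was 0.42 in replicate 2. DNAJB1 fell from 167 ± 3.57 CPM (SD, n = 3) to 57.2 CPM in replicates 1 and 3 and was at 106 CPM in replicate 2, DNAJB9 fell 1.45-fold, and DNAJC10 and DNAJC8 rose 1.24-fold and 1.26-fold, with 1.57-, 1.13- and 2.39-fold of the control for these 3 in replicate 2. Of 13 chaperonin and prefoldin subunits, which fold actin and tubulin, 1 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.902): CCT8 fell 1.19-fold but was 2.93-fold of the control in replicate 2, CCT4 fell 1.10-fold with 1.41-fold in replicate 2, and PFDN1 rose 1.17-fold, while PFDN2 did not pass the test (adjusted p = 0.0574). Over all 6 libraries this list was higher by camera (adjusted p = 0.00993 and adjusted p = 0.78 with an estimated correlation), with a median log2 ratio of 1.14 in replicate 2.

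Proteasome subunits were higher: 20 of 34 rose and 1 fell (20 and 1 adjusted over the list alone), by small amounts such as 1.21-fold for PSMB2 and PSMD14, 1.17-fold for PSMA7 and 1.16-fold for PSMB4 (camera adjusted p = 9.93e-05 and adjusted p = 0.228 with an estimated correlation). Replicate 2 lay further in that direction, with a list median of 1.14 on the log2 scale. In that library chaperonin and prefoldin subunits, ribosomal proteins and nuclear oxidative phosphorylation genes lay as high, with medians of 1.14, 1.19 and 1.19. Without it their medians were 0.02, -0.14 and 0.05, so the proteasome value of replicate 2 is no separate evidence of a rise. With replicate 2 included, the proteasome list had a camera adjusted p of 4.77e-06 (0.701 with an estimated correlation) and a fry adjusted p of 0.386. Among ER unfolded protein response genes 12 of 30 fell and 4 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0192 and adjusted p = 0.149 with an estimated correlation). CALR, the ER chaperone calreticulin, fell 2.08-fold from 1238 to 594 CPM but stood at 1207 CPM in replicate 2. CANX fell 1.24-fold and PDIA6 1.28-fold, with 0.562- and 1.27-fold in replicate 2, whereas XBP1 rose 1.35-fold. HSPA5, the ER chaperone BiP, and DDIT3 did not pass the test (log2 fold changes of -0.04 and -0.16) but lay at 1.43- and 2.98-fold of the control in replicate 2 (1.07- and 2.22-fold with library totals). The list's median in replicate 2 was 0.37 above the control mean, and the call was lost with that library included (adjusted p = 0.95).

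ATF4 targets of the integrated stress response, which serve amino acid supply under stress, rose in larger numbers than those of any other list tested: 34 of 39 rose and 0 fell, also adjusted over the list alone. STC2 rose 1.80-fold, from 100 ± 2.52 CPM (SD, n = 3) to 181 CPM in replicates 1 and 3 with 130 CPM in replicate 2, DDIT4 1.55-fold, and SLC3A2, a subunit of amino acid transporters, 1.37-fold. SLC7A11, the cystine transporter, rose by a log2 value of 0.58, with 0.967-fold in replicate 2. ATF4 mRNA itself had a log2 fold change of 0.05 (edgeR adjusted p = 0.299), but in replicate 2 it stood at 1243 CPM, 1.78-fold of the control (1.33-fold with library totals). The list was higher by camera without replicate 2 (adjusted p = 2.53e-12 and adjusted p = 0.109 with an estimated correlation) and with it (adjusted p = 7.32e-07 and adjusted p = 0.0689 with an estimated correlation), and its median log2 ratio in replicate 2 was 0.25, beside 0.26 in the 5-library fit, and -0.17 with library totals. Autophagy and lysosome genes also rose more often than they fell, 16 against 6 of 36 (18 and 6 adjusted over the list alone; camera adjusted p = 0.00607 and adjusted p = 0.118 with an estimated correlation). The cathepsin genes CTSD, CTSZ and CTSB rose 1.55-, 1.31- and 1.28-fold and GRN, which encodes progranulin, 1.30-fold with 0.739-fold in replicate 2. The list's median in replicate 2 was 0.25.

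**Figure D3:**
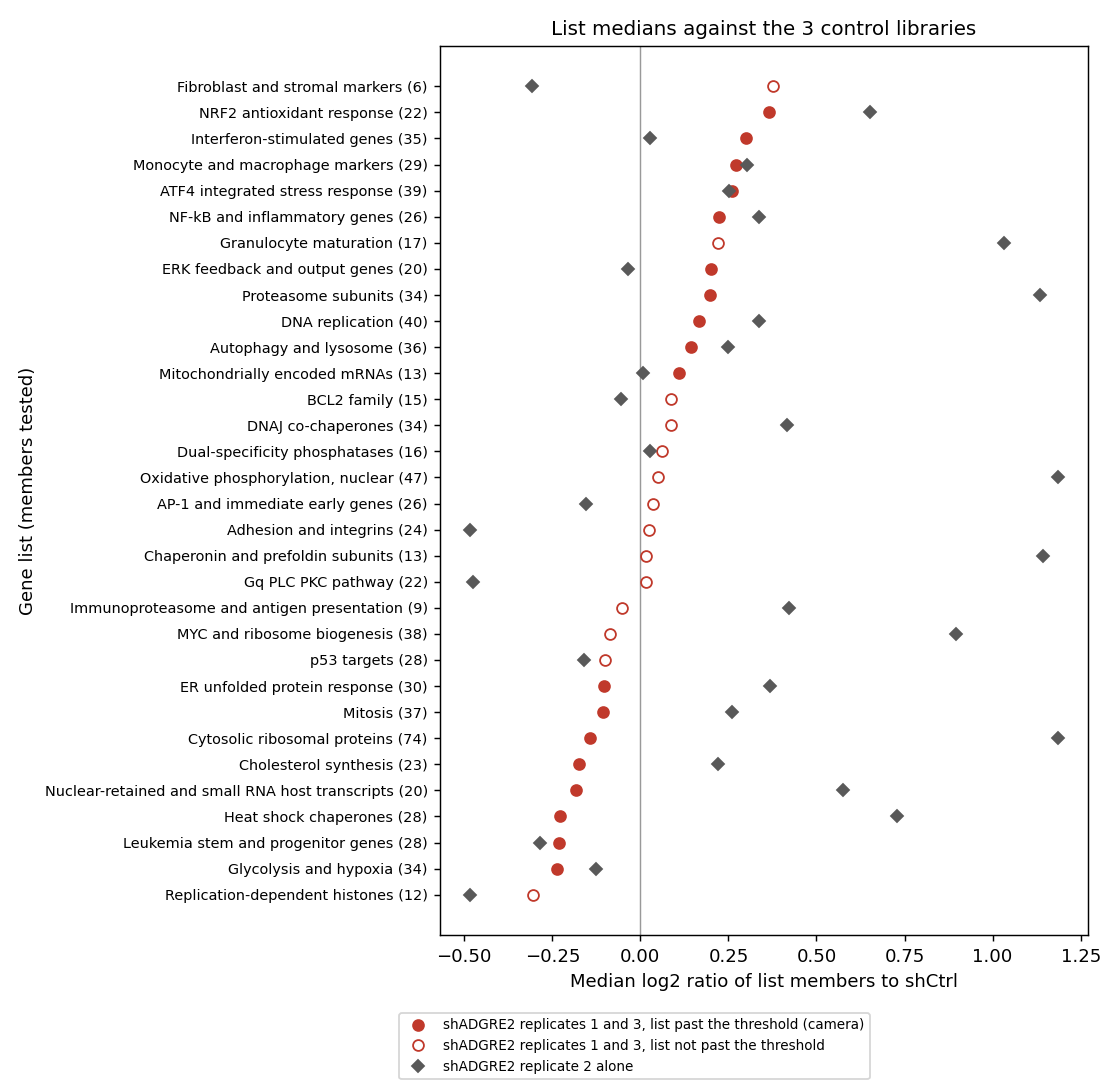
Median log2 ratio to the control libraries for each of the 32 tested gene lists, as circles for the fit without shADGRE2 replicate 2 (filled where camera with the preset correlation passed the threshold) and as diamonds for shADGRE2 replicate 2 alone. Cytosolic ribosomal proteins and heat shock chaperones lie on opposite sides of 0 in the 2 measures, at -0.14 and 1.19 and at -0.23 and 0.73, while ATF4 targets lie at 0.26 and 0.25.

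Signalling genes linked to G-protein-coupled receptors moved in both directions. Of 26 AP-1 and immediate early genes, 9 rose and 9 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.616), and the median (0.04) and mean (-0.10) had opposite signs. JUN fell by 2.44 on the log2 scale and FOS by 1.24, with replicate 2 at 0.397- and 0.781-fold of the control mean. KLF2 fell 1.97-fold, and IER5 fell 1.47-fold with 1.33-fold in replicate 2. JUNB rose 1.14-fold, MYC fell 1.13-fold and FOSL1 did not pass the test (adjusted p = 0.549). Dual-specificity phosphatases, which switch off MAP kinases, also split, with 5 of 16 up and 3 down (5 and 4 adjusted over the list alone; camera adjusted p = 0.794): DUSP1 fell 2.79-fold from 18.1 ± 1.19 CPM (SD, n = 3) to 6.44 CPM in replicates 1 and 3 and stood at 13.3 CPM in replicate 2, DUSP3 fell 1.38-fold, and DUSP5 and DUSP6 rose 1.71-fold and 1.47-fold.

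ERK feedback and output genes, which report MAP kinase activity, rose in 8 of 20 cases and fell in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00189 and adjusted p = 0.109 with an estimated correlation). Besides DUSP5 and DUSP6, TRIB2 rose 2.28-fold and EMP1 3.56-fold, the last from 0.946 CPM. The list's median in replicate 2 was -0.03. In the Gq, PLC and PKC pathway 3 of 22 genes rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.616). GNA15, a Gq-class subunit of blood cells, fell 1.85-fold with replicate 2 at 1.06-fold of the control, RASGRP2 fell 1.34-fold, and the kinases PRKCA and PRKCD rose 1.56- and 1.21-fold, with 0.461- and 0.893-fold in replicate 2. The list's median was 0.02 without replicate 2 and -0.47 in it.

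Monocyte and macrophage markers rose in 16 of 29 cases and fell in 4 (17 and 5 adjusted over the list alone; camera adjusted p = 0.00012 and adjusted p = 0.109 with an estimated correlation). LYZ, lysozyme, rose 1.52-fold from 1034 ± 17.5 CPM (SD, n = 3) to 1566 CPM in replicates 1 and 3 but stood at 496 CPM in replicate 2, and S100A9, a calcium-binding protein of myeloid cells, rose 2.43-fold with 6.83-fold in replicate 2. The list's median in replicate 2 was 0.30. Granulocyte maturation genes rose in 8 of 17 and fell in 4 cases (9 and 5 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.07), while over all 6 libraries they were higher (adjusted p = 0.00368 and adjusted p = 0.118 with an estimated correlation) with a median of 1.03 in replicate 2. The NADPH oxidase genes CYBB and NCF1 rose 1.57- and 2.11-fold. NCF1 has near-identical pseudogenes and is uncertain. Of 28 leukemia stem and progenitor genes, 11 fell and 4 rose (13 and 4 adjusted over the list alone; camera adjusted p = 0.0019 and adjusted p = 0.109 with an estimated correlation). GATA2, a transcription factor of blood progenitors, fell 3.22-fold but was 1.51-fold of the control in replicate 2, MYB fell 1.48-fold with 1.77-fold in replicate 2, FLT3, a receptor kinase, fell 1.91-fold with 0.494-fold in replicate 2, and AKR1C3 rose 3.99-fold.

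Inflammatory and interferon genes were higher. NF-kB and inflammatory genes rose in 10 of 26 cases and fell in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00189 and adjusted p = 0.109 with an estimated correlation), with CXCL8, which encodes interleukin-8, up 2.02-fold and TNFAIP2 up 1.35-fold. In replicate 2 these were at 2.93- and 0.477-fold of the control, and the list's median was 0.34. Interferon-stimulated genes rose in 15 of 35 cases and fell in 2 (18 and 2 adjusted over the list alone; camera adjusted p = 0.000151 and adjusted p = 0.109 with an estimated correlation). OAS3, OAS2 and IFI6 rose 1.82-, 1.71- and 1.64-fold and GBP2 fell 3.58-fold. In replicate 2, OAS3, OAS2, IFI6 and GBP2 lay at 0.653-, 0.629-, 2.12- and 1.11-fold of the control and the list's median was 0.03. Of 9 immunoproteasome and antigen presentation genes tested, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.49). CIITA, the master regulator of MHC class II genes, fell 2.21-fold and its target CD74 1.41-fold, with 0.125- and 0.377-fold in replicate 2, while B2M and NLRC5 rose 1.14- and 1.13-fold, with 3.56- and 0.442-fold in replicate 2. Adhesion and integrin genes rose in 7 of 24 cases and fell in 5 (9 and 6 adjusted over the list alone; camera adjusted p = 0.49), with THBS1 up 1.82-fold, PECAM1 up 1.32-fold, ITGA7 down 1.37-fold and CD44 down 1.30-fold. In replicate 2, THBS1 and PECAM1 were at 0.833- and 0.670-fold and CD44 at 1.23-fold of the control.

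Genes of the hypoxia response and of glycolysis fell in 19 of 34 cases and rose in 5 (19 and 7 adjusted over the list alone). Besides ALDOC, BNIP3, a mitophagy receptor, fell 3.56-fold, P4HA1, a collagen prolyl hydroxylase, 2.65-fold and NDRG1 1.82-fold. In replicate 2 these lay at 1.38-, 1.11- and 0.772-fold of the control. The list was lower by camera without replicate 2 (adjusted p = 3.16e-05 and adjusted p = 0.109 with an estimated correlation) and with it (adjusted p = 0.000583 and adjusted p = 0.114 with an estimated correlation). NRF2 targets of the antioxidant response rose in 14 of 22 cases and fell in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 9.67e-07 and adjusted p = 0.109 with an estimated correlation). ME1, NQO1 and the ferritin gene FTH1 rose 2.57-, 2.15- and 1.78-fold, with 2.70-, 2.07- and 0.803-fold in replicate 2. Cholesterol synthesis genes fell in 7 of 23 cases and rose in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.00189 and adjusted p = 0.109 with an estimated correlation), among them DHCR7 by 1.53-fold, INSIG1 by 1.34-fold and FDFT1 by 1.31-fold. In replicate 2 these lay at 0.325-, 1.17- and 1.59-fold of the control, and the list median was 0.22. With that library included the list was not called (camera adjusted p = 0.453), with 13 members higher and 10 lower, a median of 0.018 and a mean of -0.035. Of 47 nuclear oxidative phosphorylation genes 10 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.161), such as ATP5PF, up by 0.26 on the log2 scale, and UQCRC2, down 1.12-fold with 1.26-fold in replicate 2. The median was 1.19 in replicate 2, and over all 6 libraries the list was higher (camera adjusted p = 5.71e-05 and adjusted p = 0.78 with an estimated correlation).

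DNA replication genes rose in 20 of 40 cases and fell in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 0.00012 and adjusted p = 0.109 with an estimated correlation). The helicase genes MCM6 and MCM5 rose 1.28- and 1.24-fold and CDT1, which helps to load the helicase, fell 1.26-fold, with 1.31-, 0.966- and 0.962-fold in replicate 2. The list's median in replicate 2 was 0.34. Mitosis genes moved the other way, with 12 of 37 down and 2 up (13 and 2 adjusted over the list alone; camera adjusted p = 0.00229 and adjusted p = 0.231 with an estimated correlation): HMMR and CENPA fell 1.40-fold each, and BUB1 fell 1.22-fold, with 0.892-, 1.38- and 0.811-fold in replicate 2, and the list's median in replicate 2 was 0.26. With replicate 2 included the mitosis list was not called (camera adjusted p = 0.453), with 21 members higher and 16 lower, a median of 0.046 and a mean of -0.0064. Cytosolic ribosomal proteins fell in 52 of 74 cases and rose in 0 (59 and 0 adjusted over the list alone), by 1.18-fold for RPL13 and RPL12, 1.17-fold for RPS25 and 1.16-fold for RPL14 (camera adjusted p = 1.34e-08 and adjusted p = 0.33 with an estimated correlation). In replicate 2 these 4 lay at 2.17-, 1.35-, 2.57- and 1.92-fold of the control and the list's median was 1.19, and with that library included their direction turned, with a median log2 fold change of 0.45 (camera adjusted p = 0.00164 and adjusted p = 0.803 with an estimated correlation). Many of them have processed pseudogenes and are uncertain. Of 38 MYC and ribosome biogenesis genes 11 fell and 4 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.0603), with HSPD1 down 1.27-fold, MYBBP1A down 1.24-fold, FBL down 1.15-fold and TFAM up 1.17-fold. In replicate 2 these lay at 2.39-, 0.536-, 3.23- and 1.96-fold of the control. The median in replicate 2 was 0.90. Targets of p53 fell in 11 of 28 cases and rose in 5 (12 and 5 adjusted over the list alone; camera adjusted p = 0.08): PHLDA3 and MDM2 fell 1.51- and 1.26-fold, and CDKN1A and TNFRSF10B rose 1.33- and 1.30-fold, with 0.908- and 0.562-fold in replicate 2. In the BCL2 family 4 of 15 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.616), with opposite signs of median (0.09) and mean (-0.02). BCL2, which blocks apoptosis, fell 2.01-fold with 0.757-fold in replicate 2, and BCL2A1 and MCL1 rose 2.10- and 1.16-fold, with 6.24- and 0.951-fold in replicate 2.

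Markers of other cell types were counted in every library. Erythroid, megakaryocyte, B and plasma cell and epithelial markers summed to at most 44.6, 39.4, 5.34 and 39.9 CPM in any library, and each had too few tested members for a list test. Of 3 epithelial markers tested ESRP1 rose 1.70-fold and CLDN7 1.58-fold, with 0.343- and 1.58-fold of the control in replicate 2. Of 4 megakaryocyte markers tested ITGA2B fell 2.33-fold, from 2.83 CPM, with 0.977-fold in replicate 2. T and NK cell markers reached 263 CPM, mostly from NCAM1 (162 CPM on average). NCAM1 and NKG7 fell by 0.13 and 0.17 on the log2 scale. In replicate 2 NCAM1 was at 0.403-fold of the control and NKG7 at 84.3 CPM, beside 70.2 CPM in the controls. Of 6 fibroblast and stromal markers tested 2 rose, SPARC 1.64-fold and COL6A3 2.78-fold, and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.192); in replicate 2 they lay at 1.00- and 0.781-fold of the control. Transcripts tied to RNA quality shifted slightly: of 13 mitochondrially encoded mRNAs 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0337 and adjusted p = 0.589 with an estimated correlation), and of 20 nuclear-retained and small RNA host transcripts 11 fell and 3 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.0201 and adjusted p = 0.157 with an estimated correlation). MT-ND6 and MT-CYB rose by 0.28 and 0.22 on the log2 scale, and MALAT1 and SNHG6 fell by 0.45 and 0.35, and in replicate 2 these lay at 1.14-, 0.717-, 0.670- and 3.21-fold of the control. The medians of these lists in replicate 2 were 0.01 and 0.58, and neither list was called with that library included (camera adjusted p = 0.481 and 0.776). Of 12 replication-dependent histone genes 1 rose, H4C9, and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.124).

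Counted over lists, camera called 15 of 32 tested lists in all 6 libraries, 13 higher and 2 lower, and 18 without shADGRE2 replicate 2, 10 higher and 8 lower. The calls of both fits shared 11 lists in the same direction: ATF4 targets, NRF2 targets, proteasome subunits, autophagy and lysosome genes, DNA replication, interferon-stimulated, NF-kB, ERK feedback and monocyte genes were higher, and glycolysis and leukemia stem genes were lower. Both fits hold the same 5 libraries, so this overlap is not independent evidence. Of these lists, fry over all 6 libraries did not call proteasome subunits, ERK feedback or interferon-stimulated genes (fry adjusted p = 0.386, 0.255 and 0.12). With an estimated correlation camera called 0 lists in either set, with smallest adjusted p of 0.0689 and 0.109, and fry called 12 and 23.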

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

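Both the libraries that enter and the method change the number of genes called; quality weights, length and GC offsets, and every alternative run on the 5 libraries without shADGRE2 replicate 2 were chosen after the data were seen, and the cause was not tested except where stated. Over all 6 libraries edgeR's count of 0 (1482 at an unadjusted p under 0.05) became 343 with DESeq2 (122 at 2-fold or more), 3412 with quality weights (423), 17 with length and GC offsets (14), 8 without a filter (8), and 1 each with upper quartile normalization (1) and with at least 10 CPM in 3 libraries (1); limma voom gave 0. It stayed 0 under the other normalizations, filters and dispersion settings run. Leaving out 1 library gave 0 to 3873 calls and 0 to 406 at 2-fold or more, the highest in both cases without shADGRE2 replicate 2. All 343 DESeq2 genes, all 17 genes with offsets and 3192 of the 3412 with quality weights were among the 3873, each in the same direction. Each of these fits holds the 5 libraries that gave the 3873, so this overlap is not independent evidence. The replicate numbers share only a number: same-numbered libraries deviated with r of -0.12, -0.09 and 0.04, and a fit with the replicate block called 0 genes and 14 lists and gave ADGRE2 a log2 fold change of -1.10. ADGRE2 stayed lower in every alternative. Its adjusted p ran from 2.99e-07 to 0.831 over the alternatives to the 6-library fit and from 1.45e-16 to 1.44e-05 over those to the 5-library fit. It passed the threshold with DESeq2 (-1.08; adjusted p = 0.000368), with quality weights (-0.90; adjusted p = 6.18e-06) and without shADGRE2 replicate 2, and its leave-one-out values ran from -1.18 to -0.90. Camera's 15 lists became 0 with an estimated correlation and 12 to 18 when 1 library was left out. Over the 5 libraries, 3873 became 888 in a test against a 1.2-fold change, which asks for more, and 406 became 268 there, 250 with DESeq2 and 82 with at least 10 CPM in 3 libraries, which tests fewer genes. Leaving out another library gave 2773 to 3392 calls, 333 to 390 at 2-fold or more, ADGRE2 values of -0.94 to -0.85 and 17 to 18 lists; with 1 knockdown library left, that library is assumed to vary like the others. Camera's 18 lists became 0 with an estimated correlation. Of 139 named genes called in the 5-library fit, 53 no longer passed against a 1.2-fold change and at most 11 in any other alternative without replicate 2, and none of these changed sign. With shADGRE2 replicate 2 included 121 lost their call and 16 changed sign: CCT8 (0.62), CCT4 (0.10), FBL (0.72), FDFT1 (0.051), HSPB1 (0.24), HSPD1 (0.40), MYB (0.053), RPL12 (0.019), RPL13 (0.37), RPL14 (0.28), RPS25 (0.51), SNHG6 (0.67), UQCRC2 (0.016), ADGRE4P (-0.11), MT-CO1 (-0.039) and NLRC5 (-0.16). Of the 18 lists 11 kept their call, 4 lost it (mitosis, cholesterol synthesis, mitochondrially encoded mRNAs, and nuclear-retained and small RNA host transcripts) and 3 turned, with medians of 0.19 for heat shock chaperones, 0.074 for the ER unfolded protein response and 0.45 for ribosomal proteins. List tests were not run with DESeq2, limma voom, quality weights, robust dispersion, the 1.2-fold test or the offsets. Depth limits low genes most: the SE of the log2 fold change was 0.419 for ADGRE3 and 0.463 for COL6A3, beside 0.036 for HSPA8.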

Other observations

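All tests in this part were chosen after the values were seen, except the length and GC test of heat shock chaperones and the counts of other splits. Grouping the 5-library result by the letters that open a gene symbol gave 169 families with at least 10 tested genes, and camera called 7 of them. HOXA genes, which encode homeobox factors active in leukemia, were lower in 12 of 13 cases (adjusted p = 0.00441 and adjusted p = 0.951 with an estimated correlation), and 3 of them fell by edgeR: HOXA5 from 20.2 CPM to 11.3 and 14.7 CPM, HOXA9 from 48.1 to 40.6 and 39.8 CPM and HOXA11 from 2.32 to 1.07 and 1.02 CPM. In shADGRE2 replicate 2 these 3 lay above the control at 1.14-, 1.22- and 2.98-fold, while HOXA6, HOXA7 and HOXA-AS3 lay far below it at 0.0186-, 0.0549- and 0.032-fold and the family's median log2 ratio was -0.29, beside -0.61 in the 5-library fit. Of the 13 genes, 4 are antisense genes. Pairs that overlap a partner were not counted and the strand was not used, so values of these 4 and of their partners are uncertain. Matrix metalloproteinase genes moved the other way (adjusted p = 0.00441 and adjusted p = 0.951 with an estimated correlation), with 7 of 13 up and 0 down, antisense genes among them. MMP14, which encodes a membrane-bound collagenase, rose from 444 ± 12.2 CPM (SD, n = 3) to 725 and 729 CPM, with 710 CPM in replicate 2, and MMP25 rose from 23.0 to 63.2 and 63.3 CPM, with 50.3 CPM in replicate 2. MMP2 and MMP25-AS1, which also rose, lay at 0.658- and 0.803-fold of the control in replicate 2, where the family's median was 0.15, beside 0.63 in the 5-library fit. The elongation factor genes EEF2 and EEF1A1 fell by 0.26 and 0.12 on the log2 scale, with replicate 2 at 0.583-fold and 2.03-fold of the control. Of 19 genes whose symbols open with EEF, 9 fell (camera adjusted p = 0.0104 and adjusted p = 0.951 with an estimated correlation). Pseudogenes such as EEF1A1P5 and genes of modifying enzymes such as EEF2K are among the 19, so they are not all elongation factors. The family's median log2 ratio in replicate 2 was 0.65, opposite in sign to its median of -0.26 in the 5-library fit.

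Beside the other knockdown libraries, shADGRE2 replicate 2 had more mRNA of ribosomal proteins (median 2.53-fold over 74 genes) and nuclear oxidative phosphorylation genes (2.27-fold). It also had more of chaperonin subunits (a median log2 ratio of 1.14), heat shock chaperones (1.99-fold) and proteasome subunits (1.97-fold). For MYC and ribosome biogenesis genes the median was 1.77-fold. Each of these medians lay above 99.95% to 100% of 10000 random lists matched on expression. Replicate 2 had less mRNA of adhesion and integrin genes (median 0.626-fold, above 0.06% of random lists) and of Gq, PLC and PKC pathway genes (0.702-fold, above 1.24%). These lists were picked by the same ratio. Random genes were drawn independently, whereas genes of a list move together, and replicate 2 is 1 library, so these shares do not test a list. ATF4 and NRF2 targets were at 0.997- and 1.01-fold. In the major histocompatibility complex RPS18 had 55 counts over the 6 libraries, where the median of 73 other ribosomal protein genes was 148890, and PSMB8, PSMB9 and TAP1 had 2, 5 and 1.

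Why shADGRE2 replicate 2 stands apart remains open. Exon length and GC content explain 16.1% of its deviations across genes, and once they were removed its highest correlation with another library was 0.945, below the lowest of 0.987 among the other 5. Random loss of molecules would spare abundant genes, but the SD of its log2 ratios was 0.842 at 100 CPM or more and 0.981 at 1 to 10 CPM, where the other 5 libraries had 0.117 to 0.181 at 100 CPM or more. A control library under the wrong label would carry control levels of ADGRE2, and its level corrected for length and GC content was 12.2 CPM, beside 22.4 to 25.8 CPM in the controls and 13.01 and 12.5 CPM in the other knockdown libraries. A different state of those cells, a different hairpin or a different handling of that library may remain, and the labels name none of these.

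The rise of CD14, MERTK and CCL2 could come from monocytes in the cultures. S100A12, VCAN and FCN1, which monocytes carry in abundance, reached at most 2.04 CPM in replicates 1 and 3, while CD14 gained 25.2 and 26.4 CPM, so admixed monocytes are argued against in these libraries, although VCAN rose from 0.905 to 1.84 and 2.04 CPM (edgeR adjusted p = 0.0238). The transcripts were chosen after an earlier set, which held MHC genes with almost no counts, had been seen, and FCER1G and TYROBP, also abundant in monocytes, gained 42.1 and 28.9 CPM, whereas CD74 fell and CST3 differed by -8.31 CPM. In replicate 2, S100A12, VCAN and FCN1 stood at 5.52, 4.71 and 0.325 CPM, beside control means of 0.614, 0.905 and 0.0786 CPM. CD14 was at 16.4 CPM there, beside 7.03 CPM in the controls, so the argument does not extend to replicate 2. Length and GC content are argued against too, since 16 of the 16 monocyte genes that rose also rose with the offsets. A partial shift of the leukemia cells toward a monocytic state is a hypothesis that was not tested further: in replicate 2 the list's median was 0.30 (-0.096 with library totals), beside 0.27 in the 5-library fit, with S100A9 at 6.83-fold and LYZ at 0.480-fold of the control.

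Heat shock chaperones were lower in replicates 1 and 3 and higher in replicate 2. After the length and GC correction the list's median log2 ratio in replicate 2 was 0.57 (standard error over members 0.113) with TMM and 0.15 (0.113) with library totals, so that trend alone does not account for the opposite direction under TMM, while the size depends on the scaling. Counts taken by a few abundant genes remain open: library totals move all genes alike, so their median of 0.31 (0.117) does not bear on this, nor does 0.68 (0.122) without the 50 most abundant genes. A response of chaperone genes that differs between samples may be at work, and with 1 library of that kind it cannot be set apart from the other deviations of replicate 2.

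Other splits of the same libraries are too few for a share under 0.05. Among the 10 splits of 6 libraries the real one gave 0 genes and the highest other 0, at 2-fold or more likewise 0 and 0 (10 of 10 splits as large in both cases), and 15 lists against a highest other of 15 (3 of 10 splits as large). Among the 10 splits of 5 libraries the real one gave 3873 genes and the highest other 2, and 18 lists against a highest other of 17 (1 of 10 splits as large in both cases). The splits with 15 lists exchanged shADGRE2 replicate 2 with a control, and those with 13 to 17 set 2 controls against the rest, which keeps part of the real contrast.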
